A study of Mus musculus with 4 samples.

How the data were processed

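KDM5A was precipitated from mouse ES cells of strain C57BL/6, 2 samples of Kdm5a f/f cells and 1 of Kdm5a KO cells, and input DNA of f/f cells served as a further library. Per the labels' protocols, the cells were kept on irradiated fibroblast feeders and moved to gelatin for ChIP, libraries were amplified for 18 PCR cycles, fragments of about 320 bp including adaptors were cut from a gel, and sequencing was done on the Genome Analyzer. The submitters' processing notes name Bowtie and the mouse assembly mm9. The Bowtie version, its settings, the peak caller, its control and its threshold are not given in the sources used here. The authors deposited mapped reads of 36 bp for 3 read sets (f/f ChIP, KO ChIP, input), 1 line per read with position and strand, and 1 list of peaks with a score per peak. The deposited score is the authors' own, its scale is not given in the sources used here, and it was used only to rank and split peaks within the list. The f/f read set holds 2 lanes and the labels do not say which lane is which sample, so lanes are given as lanes, with no mean or spread between them.

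Duplicate reads were present in the deposited sets, at 3.07% of f/f, 2.80% of KO and 3.14% of input reads, and were kept. The 5' end of each read was moved 100 bp toward the fragment centre, for a fragment taken as 200 bp, and counted in each peak or window. Counts were scaled to all mapped reads as RPM, the reads in a region divided by the library's mapped reads and multiplied by 1e+06. The offset between strands at the 500 highest-scoring peaks was 100 bp in the f/f ChIP and 90 bp in the KO ChIP, shorter than the fragment assumed, so a shift of 50 bp was added as an alternative after the data were seen. At 5.38, 3.69 and 3.47 reads per kb of genome for the f/f, KO and input libraries, 3 reads in a peak stand for 0.211, 0.308 and 0.327 RPM.

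A fold was the ratio of RPM between libraries, with an exact (Clopper-Pearson) conditional binomial interval at the 95% level. A background count of 0 was replaced by 3 reads, which gives a floor value of the fold. This value can exceed the lower limit of the exact interval. A peak passed when its fold was at least 2 and its interval lay above 1, and the same rule with the libraries exchanged gave the opposite count. Shares of reads have Wilson intervals. PCR reads without molecular identifiers are not independent molecules, so intervals and floors cover counting error only. With 1 read set per condition, any difference is between these libraries, not a test of genotypes. The rule was tested on simulated counts, drawn from a Poisson distribution around the background read counts of the 3093 peaks, with 200 peaks changed. Against the KO depth it passed 43%, 75% and 90% of peaks changed 3-fold, 5-fold and 10-fold, and at most 0.553% of unchanged peaks. Against the input depth it passed 24%, 46% and 75.5%, and at most 0.311% of unchanged peaks. In the opposite direction at most 0.830% and 0.864% of unchanged peaks passed, for KO and input. These draws hold counting error only, so the rates do not cover spread between libraries or a choice of peaks on f/f reads.

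Windows of 2 kb that touch no peak were counted when they had at least 20 f/f reads and a fold of at least 4. Profiles used 50 bp bins within 2 kb of peak centres. Chromosomes were compared by their share of reads and in 1 Mb windows with at least 1000 input reads, scaled to the median window of the autosomes other than 6 and 11. The main groups of named peaks were chosen by a rule fixed before the data were examined, for the case of no gene annotation of the same assembly. They were the 10 with the highest authors' score, and the 10 with the largest f/f over KO fold among peaks with at least 20 f/f reads. Other peaks and pairs are named because of their values, not by this rule. Alternatives fixed before the data were examined were 1 read per position and strand, no shift, scaling to 10 kb windows that touch no peak, a fold of at least 4, the 1546 peaks that score above the median and, for windows, the input as background and a fold of at least 2. Alternatives added after the data were seen were the shift of 50 bp, each f/f lane alone, leaving out chromosomes 6 and 11 with either scaling, reads outside the peaks and thinning of the f/f reads with and without these chromosomes. Splits of peaks at the score quartiles and the lane comparison were also added then. Intervals of ratios over sets of peaks in the closing part come from 1000 bootstrap draws of peaks.

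The gene table at hand is of the GRCm38.p6 assembly, whose coordinates differ from mm9. Peaks were therefore not assigned to genes. Distances to transcription start sites, genes and gene lists with a peak at the start site, and reads across the Kdm5a gene, which would check the genotype labels, were planned and are not analysed here. Analyses used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.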

Results

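KDM5A (also called JARID1A or RBP2) is a histone lysine demethylase and a member of the JARID1 family. Its genomic binding sites were mapped by chromatin immunoprecipitation and sequencing (ChIP-seq) in C57BL/6 mouse embryonic stem (ES) cells. Cells carrying floxed Kdm5a alleles (Kdm5a f/f), which the submitters label wild type, were compared with Kdm5a knockout (KO) cells precipitated with the same antibody and with unprecipitated input DNA of the f/f cells. The series holds 4 samples in 3 groups: 2 KDM5A ChIP samples of f/f cells, 1 KDM5A ChIP sample of KO cells and 1 input sample. Mapped reads numbered 14207572 for the f/f ChIP, 9737027 for the KO ChIP and 9174595 for the input. The f/f reads came from 2 sequencing lanes, of 4706913 reads (lane 1) and 9500659 reads (lane 2), which the labels do not tie to the 2 samples. A deposited list of 3093 peaks covered 1123.5 kb, or 0.0425% of the sequence spanned by reads. Median peak width was 321 bp (quartiles 245 and 447 bp), and the authors' peak score ran from 50.01 to 822.81 with a median of 60.55. With 1 read set per condition, the differences have no replicate check, no p-values are given, and all intervals are 95% and cover counting error only.

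The f/f and KO cells were compared to find sites whose ChIP signal was lower in cells labelled Kdm5a knockout. Reads of the f/f ChIP gathered in sharp maxima at the listed sites, and far fewer reads of the KO ChIP did. The peaks took up 0.481% of f/f reads (Wilson interval 0.478 to 0.485%), 0.140% of KO reads (0.138 to 0.143%) and 0.0685% of input reads (0.0669 to 0.0702%). The f/f share was thus 3.43 times the KO share (exact interval 3.37 to 3.50), with 5.37 in lane 1 and 2.47 in lane 2. Read density in the peaks was 11.3 times the genome mean in the f/f ChIP, 3.30 times in the KO ChIP and 1.61 times in the input. At the peak centres the f/f ChIP averaged 0.257 RPM (reads per 1e+06 mapped reads) per 50 bp bin, against 0.0616 in the KO ChIP and 0.0257 in the input. At 1 to 2 kb from the centres the libraries lay close together, at 0.0245, 0.0258 and 0.0235 RPM per bin, in the same order.

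**Figure D1:**
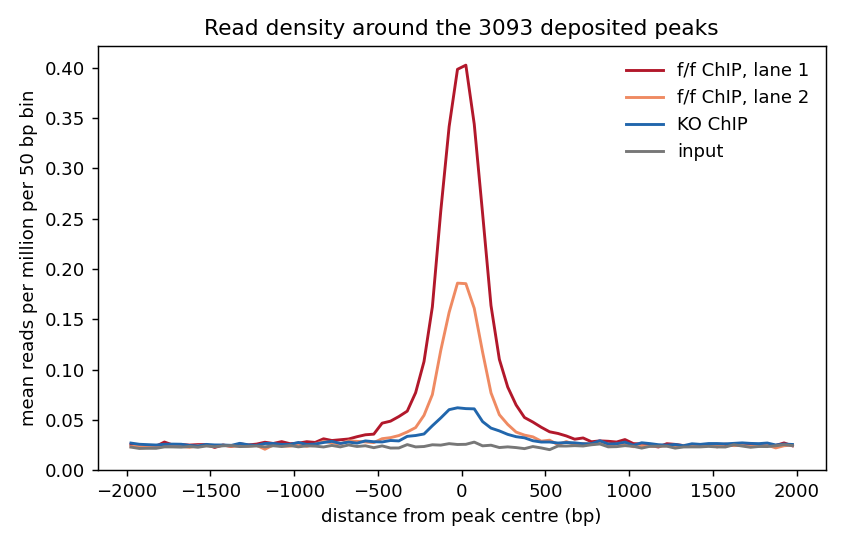
Mean RPM per 50 bp bin (vertical axis) against distance from the centre of the 3093 deposited peaks in bp (horizontal axis), with 1 line each for lanes 1 and 2 of the f/f ChIP, the KO ChIP and the input. The 2 bins at the centre average 0.400 in lane 1, 0.186 in lane 2, 0.0616 in the KO ChIP and 0.0257 in the input.

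Of the 3093 peaks, 1480 (47.8%) had at least 2-fold higher RPM in the f/f than in the KO ChIP with an interval above 1, and 0 met the same rule in the opposite direction. The list carries the name of the f/f ChIP. If it was called from f/f reads, few of its peaks could pass in the opposite direction, so the 0 says little. The median fold over the KO ChIP was 3.43 (quartiles 2.06 and 5.83), with the 292 peaks that had no KO read entered at their floor value. The passing share rose with the score. When the list was cut at the score quartiles, 702 of the 774 peaks in the top class (90.7%) passed, with a median of 2.46 RPM in the f/f and 0.411 RPM in the KO ChIP. The next class had 382 of 773 (49.4%), the one after it 232 of 775 (29.9%), and the lowest-scoring class 164 of 771 (21.3%). The top class also held 50.5% of all f/f reads in peaks. From the lowest to the top class, median width rose from 250 to 500 bp and median f/f level from 0.704 to 2.46 RPM. The power to pass rose with them. If the score was computed from these f/f reads, part of the rise is built in. Depth limited these calls, since the median peak held 15 f/f reads and 3 KO reads, and peaks simulated with a true 3-fold difference passed in 43% of cases. Lane 2 alone gave 788 peaks and lane 1 alone 1635, from a setting added after the data were seen.

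**Figure D2:**
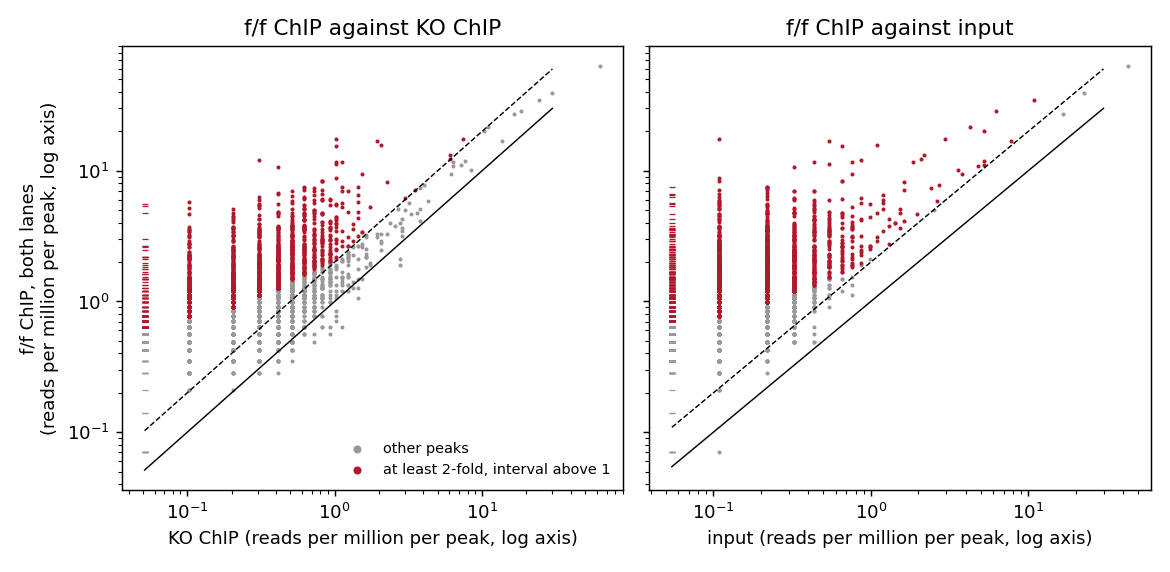
RPM per peak in the f/f ChIP (vertical log axis) against the KO ChIP (left, horizontal log axis) and the input (right, horizontal log axis), with 1 point per deposited peak, red where the f/f value is at least 2-fold higher and the interval lies above 1. Dashes at the left edge are peaks with 0 background reads, 4 peaks with 0 f/f reads are not drawn, the solid line marks equal values and the dashed line a 2-fold difference; 1480 peaks are red against the KO ChIP and 1995 against the input.

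The 10 peaks with the highest authors' scores all passed over both backgrounds, at 8.58 to 39.1 times the KO level. Positions are given in the mm9 assembly. The highest-scoring peak, on chromosome 15 from 76437534 to 76438176, had 17.6 RPM in the f/f ChIP, 1.03 in the KO ChIP and 0.109 in the input. It was thus 17.1-fold over KO (exact interval 9.16 to 36.2). The peak on chromosome 19 from 3282558 to 3283382 reached 15.3 RPM, 14.9-fold over KO (7.97 to 31.6). On chromosome 1, the peak from 88483393 to 88484095 had 10.7 RPM and was 26.0-fold over KO (9.97 to 96.8). Chromosome 4 held a pair of these peaks. One, from 153348749 to 153349702, had 16.8 RPM and kept the highest KO level of the group, 1.95 RPM, for an 8.58-fold difference (5.38 to 14.5). The other, from 133130418 to 133131140, was 10.9-fold over KO (5.77 to 23.2). The peak on chromosome 7 from 133520407 to 133521150 combined 12.04 RPM in the f/f ChIP with 3 KO reads, a ratio of 39.1 (13.1 to 191). The remaining peaks of the group lay on chromosome 8 from 13104351 to 13105041 (11.3-fold), chromosome 6 from 108135201 to 108135739 (13.7-fold), chromosome 3 from 85377864 to 85378458 (11.7-fold) and chromosome 5 from 3595685 to 3596780 (10.3-fold). All 10 had a higher RPM in lane 1 than in lane 2 of the f/f ChIP, and their folds over KO were 16.0 to 63.4 in lane 1 and 4.91 to 27.0 in lane 2.

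**Figure D3:**
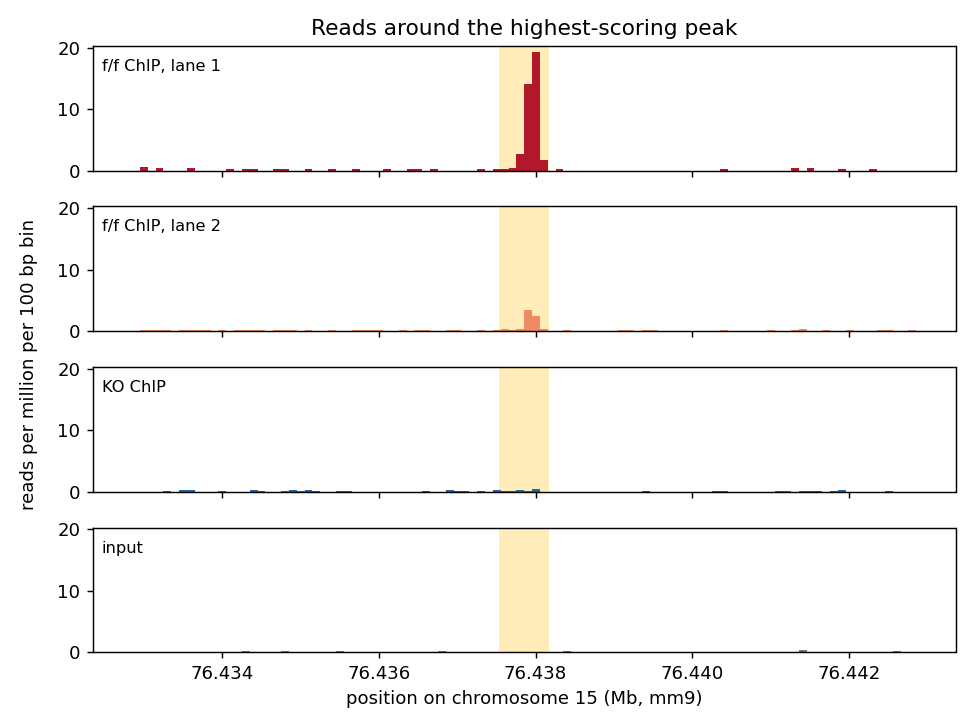
RPM per 100 bp bin (vertical axes, same scale) along chromosome 15 in Mb of mm9 (horizontal axis) around the highest-scoring peak, with 1 panel each for f/f ChIP lanes 1 and 2, the KO ChIP and the input; shading marks the deposited peak, from 76437534 to 76438176. Over the peak, lane 1 has 38.5 RPM, lane 2 has 7.26, the KO ChIP 1.03 and the input 0.109.

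A second group was formed by the 10 peaks with the largest f/f over KO ratio among those with at least 20 f/f reads. A KO count of 0 was entered as 3 reads, which ranks such peaks below those with 1 KO read, so the group holds only peaks with KO reads. The 29 peaks with at least 20 f/f reads and no KO read have only floor values. The highest of these belonged to chromosome 16 from 84735185 to 84735757, where 79 f/f reads gave 18.0-fold over KO by the floor of 3 reads. Its lower limit by the exact interval was 14.3. By lane its floor value was 29.7 in lane 1 and 12.3 in lane 2, and other such peaks were higher, at 36.5 in lane 1 and 13.7 in lane 2. Ranking by this ratio itself selects peaks with few KO reads. In the ranked group the KO ChIP had 1 to 3 reads per peak, while the f/f ChIP had 3.24 to 12.04 RPM. Their ratios ran from 31.5 to 56.2, with wide intervals because of the few KO reads. By lane they were 53.8 to 120 in lane 1 and 9.22 to 30.7 in lane 2. The largest ratio of the group, 56.2 (9.81 to 2246), belonged to chromosome 2 from 151319810 to 151320462, with 82 f/f reads and 1 KO read. It was followed by chromosome 1 from 54495618 to 54496000, at 50.7 (8.82 to 2030), and chromosome 13 from 100894610 to 100895207, at 45.2 (7.84 to 1813). The chromosome 7 peak from 133520407 to 133521150 was the only member of both groups. Ratios were 36.3 on chromosome 16 from 4683955 to 4684457, 35.0 on chromosome 5 from 124022684 to 124023172 and 34.3 on chromosome 13 from 53472396 to 53472873. They were 33.6 on chromosome 1 from 58642787 to 58643709, 32.9 on chromosome 2 from 101726189 to 101726718 and 31.5 on chromosome 15 from 8048782 to 8049382. The lower bound of the interval was 5.38 or more at each of the 10, with no adjustment for choosing them by the same ratio. Over the input, the same peaks were 7.75-fold to 53.0-fold higher.

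The input served as the second background, for local differences in read density that exist without precipitation. Measured against it, 1995 peaks (64.5%) were at least 2-fold higher in the f/f ChIP with an interval above 1, and 0 were in the opposite direction. The median fold over input was 5.17 (quartiles 2.83 and 8.07), with the 861 peaks without an input read at their floor value. In the top score class 762 of 774 peaks (98.4%) passed, and in the lowest 247 of 771 (32.0%). Among the peaks of the first group, the chromosome 15 peak from 76437534 to 76438176 had 250 f/f reads against 1 input read, a ratio of 161 (28.7 to 6402). The chromosome 19 peak from 3282558 to 3283382 was 23.5-fold over input (10.6 to 64.6), and the chromosome 7 peak from 133520407 to 133521150 was 13.8-fold (6.85 to 32.5). In the same order, the folds over input were 353, 40.6 and 22.4 in lane 1 and 66.6, 15.0 and 9.54 in lane 2. The share of all f/f reads in peaks was 7.02 times the input share (6.84 to 7.21). How the list was called is not given in the sources used here. If these f/f reads were used to call it, the folds at listed peaks are raised by that choice. The 0 in the opposite direction would then be largely set by it too.

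The lanes of the f/f ChIP differed in strength. Lane 1 had 0.753% of its reads in the peaks (Wilson interval 0.746 to 0.761%) and lane 2 had 0.346% (0.343 to 0.350%), a ratio of 2.17 (2.14 to 2.21). Each lane lay above the KO ChIP, with a share 5.37 times as high in lane 1 (5.27 to 5.48) and 2.47 times as high in lane 2 (2.42 to 2.52). The ratio between the lanes, both of f/f cells, was thus close to that of lane 2 over the KO ChIP. The interval of the pooled ratio, 3.37 to 3.50, does not cover this spread. The share of lane 1 was 2.83 times that of lane 2 in the top score class and 1.40 times in the lowest. To set the lanes against separate backgrounds, lane 1 was compared with the KO ChIP and lane 2 with the input. They passed 1635 and 1338 peaks, and 814 of these were shared, where independent lists would share 707. Within score classes the pattern was uneven. Among the 1546 peaks scoring above the median 737 were shared against 704, and among the other 1547 peaks 77 against 123. Spearman's rho of read density between the lanes, across peaks, which are not independent replicates, was -0.138 over all peaks, 0.0997 above the median score and -0.581 below it. Over all peaks, rho with the KO ChIP and the input was 0.201 and 0.212 for lane 2, and 0.00477 and 0.0457 for lane 1. If the list was called from the pooled lanes, that choice lowers rho between the lanes among weak peaks.

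The peaks were spread over all autosomes and thin on the X chromosome. Autosomes held 0.975 to 2.01 peaks per Mb, with chromosome 11 the densest at 245 peaks. Chromosome 11 had 1.36 times and chromosome 19 had 1.30 times the number of peaks given by their share of input reads. The X chromosome had 20 peaks where its input reads would give 78.9, a ratio of 0.253, and 6 of the 20 passed over KO. Its read density in the f/f ChIP was 0.323 times that of the autosomes other than 6 and 11. Sites there gather fewer reads, so an expectation in proportion to input reads may overstate the shortfall. Reads per chromosome were compared to look for differences in copy number between the cells. Chromosome 6 held 5.61% of f/f reads, 7.68% of KO reads and 5.74% of input reads. Chromosome 11 held 6.45%, 8.14% and 5.81%. In 1 Mb windows scaled to the other autosomes, the median KO over f/f ratio was 1.43 on chromosome 6 (147 windows, quartiles 1.36 and 1.47) and 1.31 on chromosome 11 (119 windows, quartiles 1.26 and 1.36). The medians of the 17 other autosomes lay between 0.967 and 1.03. The 418 peaks of chromosomes 6 and 11 had a median fold of 2.80 over KO and 5.17 over input, against 3.43 and 4.97 for the 2654 peaks of the other autosomes.

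**Figure D4:**
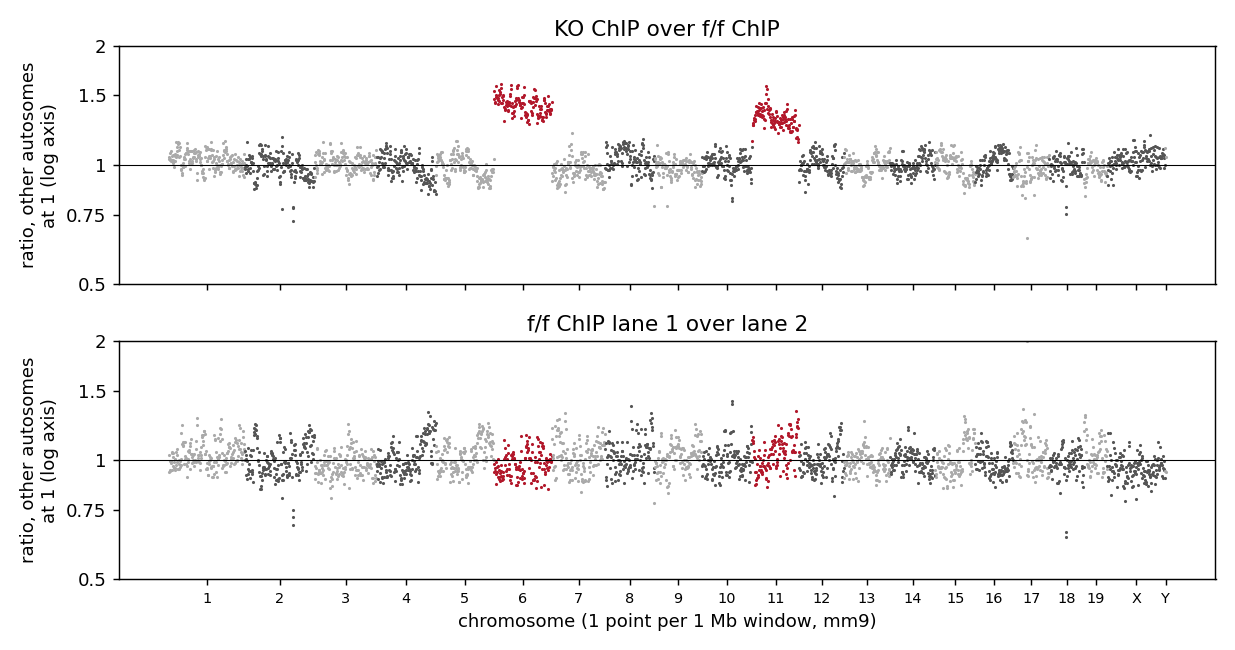
Ratio of reads in 1 Mb windows along the mm9 chromosomes (horizontal axis), with 1 point per window, for the KO over the f/f ChIP (top) and lane 1 over lane 2 of the f/f ChIP (bottom), on log axes scaled so that the median of the autosomes other than 6 and 11 is 1; 1 window outside the plotted range of the lower panel is drawn at its edge. Red points mark chromosomes 6 and 11, whose median ratios are 1.43 and 1.31 in the top panel and 0.971 and 1.045 in the bottom panel.

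Outside the list, 1105 of 1317279 windows of 2 kb had at least 20 f/f reads and a fold of at least 4 over the KO ChIP, and 157 windows met the rule in the opposite direction. Among those with a KO read, the highest fold was at chromosome 17 from 93892001 to 93894000, named after the values were seen, with 1 KO read, 1 input read and 34 f/f reads, 27 from lane 1 and 7 from lane 2. Of the 1105 windows, 1100 lay over 4 kb from any peak centre. A fold of at least 2 over the input was seen in 459, a count raised by the choice of windows on the same f/f reads. The f/f ChIP is deeper and so reaches 20 reads more easily. Random splits of the pooled f/f and KO reads at the same depths gave 603 to 687 windows over 20 draws, and 36 to 68 in the opposite direction. With the f/f reads thinned to the KO total, a setting added after the data were seen, the counts were 308 and 377, and without chromosomes 6 and 11 they were 305 and 105. When the f/f reads were thinned to the KO reads of the other chromosomes alone, these gave 197 and 126. Among the 3658 windows that touch a peak, 239 passed and 0 did in the opposite direction. A list called from f/f reads would build in much of this contrast.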

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

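The tests on chromosomes 6 and 11 and the test of positions shared between lanes were chosen after those results were seen, as were the random splits of reads and the count without peaks rich in input reads. The other tests were fixed before their results were seen.

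Chromosomes 6 and 11 stood out because the KO ChIP had more reads there than the f/f ChIP, at 1.43 and 1.31 times the ratio of the other autosomes. The ratio against windows of other autosomes with the same f/f over input ratio was 1.39, which argues against a regional bias seen between f/f and input reads. Such matching cannot exclude a regional bias of the KO library alone. On chromosomes 6 and 11, in this order, the median KO over input ratio was 1.37 and 1.51, and f/f over input was 0.968 and 1.14. The unmatched ratio of both chromosomes was 1.367 both with all reads and with 1 read per position and strand, which argues against a few stacks of duplicates. All 266 windows of both chromosomes (100%) lay above the median of the other autosomes, so the gain runs along their whole length, and extra copies of both chromosomes in a part of the KO cells, or in all of them, may explain it as a hypothesis. No karyotype was used here, and whether such a gain arose in culture or is tied to the loss of Kdm5a, which itself lies on chromosome 6, stays untested.

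The KO ChIP was flagged because its share of reads in the peaks was 2.05 times that of the input (1.99 to 2.11), although these cells are labelled as lacking Kdm5a. Its density in the peaks was 2.42 times that 1 to 2 kb from their centres (2.20 to 2.70), and 1.85 times without the 5% of peaks with the most KO reads, which argues against a regional bias without a local maximum, and the ratio over all peaks was 1.86 times the input's (1.76 to 1.98), which argues against a local bias shared with the input. The KO excess per f/f excess was 1.68 times higher on chromosomes 6 and 11 than on other autosomes (1.09 to 2.28), and 1.27 times (1.07 to 1.46) without the 206 peaks at 3 or more times the genome mean in the input. Reads carried over from the f/f libraries would lack the KO cells' higher share of these chromosomes and give a ratio of 1. The ratios above 1 argue against carry-over as the whole source but do not exclude it. Their intervals come from draws of peaks in 1 KO read set, and no such ratio was taken for other chromosomes. Across the 17 other autosomes the median fold over KO ran from 3.20 to 4.11. Antibody binding to other proteins at these sites, or a bias of ChIP toward open chromatin that input lacks, could give such an excess and cannot be parted from residual KDM5A with these libraries.

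Lane 1 of the f/f ChIP had 2.17 times the share of reads in peaks of lane 2, a signal that pooled reads hide. The ratio was 2.16 with 1 read per position and strand and 2.13 without the 5% of peaks with the most f/f reads, so neither duplicates nor a few strong peaks account for it. Lane 1 shared positions with lane 2 at 1.09 times the rate at which it shared them with the KO ChIP, while pairs at the same position within lane 1 came at 5.92 times that rate; against lane 2 with the KO ChIP, these values were 1.197 between lanes and 4.86 within lane 2. This argues against 1 DNA library run in both lanes, if the pairs within a lane are copies made in library amplification. The source of those pairs was not tested, so separate libraries of unequal enrichment remain only a possibility. No biological explanation was tested, as the labels give both f/f samples the same cells and antibody.

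Outside the list, the 1105 windows over the KO ChIP were flagged because random splits of the same reads gave at most 687. The opposite direction also exceeded the splits, with 157 against 36 to 68. Such splits hold counting error only, so an excess over them cannot tell binding from other differences between libraries. Without chromosomes 6 and 11 and with scaling to the other chromosomes, there were 987 windows against 639 to 753 in random splits, and 47 against 23 to 45 in the opposite direction. With the f/f reads thinned to the KO reads of these other chromosomes, the counts were 197 and 126.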

How the results depend on the processing

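Each of the 19 peaks named by the fixed rule stayed at least 2-fold over KO with an interval above 1 under all 6 alternatives run for it, 3 of them added later. Their folds were 4.91 to 120, which says little for the 10 chosen by their fold in the same reads. The counts of 1480 peaks over KO and 1995 over input stayed within 1.5 times under every alternative fixed beforehand that kept all 3093 peaks. They ran from 1046 to 1762 and from 1529 to 2395. Of the 1546 peaks above the median score, 1084 (70.1%) passed over KO and 1347 (87.1%) over input. In the full list the shares were 47.8% and 64.5%. Of the added ones, lane 2 alone gave 788 over KO and lane 1 alone 1635. Lane 2 held more reads than lane 1 (9500659 against 4706913) but had a lower median fold over KO, 2.56 against 4.65. These values argue against depth as the reason that lane 2 passed fewer peaks than lane 1. Why its folds were lower was not tested. The share of reads in peaks moved beyond its counting interval for the f/f and KO ChIP. For the f/f ChIP it was 0.460% with 1 read per position and strand, 0.516% without shift, 0.512% with a shift of 50 bp, 0.753% in lane 1 and 0.346% in lane 2. For the KO ChIP the first 3 of these gave 0.135%, 0.143% and 0.145%. For the input the first gave 0.0668%, outside its counting interval. No shift and the shift of 50 bp gave 0.0693% and 0.0701%, inside it. The 1105 windows outside the list became 4831 with the input as background (90 in the opposite direction) and 19100 at a fold of at least 2 (4435). They became 220 in lane 1 (1026), 283 in lane 2 (350) and 308 with f/f reads thinned to the KO total (377). Without chromosomes 6 and 11, that thinning gave 305 (105), and thinning to the KO reads of the other chromosomes 197 (126). These 5 settings hold fewer f/f reads, so fewer windows can reach 20; leaving out chromosomes 6 and 11 alone gave 1098 (40), and 987 (47) with scaling to the other chromosomes. The KO over f/f ratios of chromosomes 6 and 11 kept within 1.41 to 1.46 and 1.28 to 1.33 under 4 alternatives each, all chosen after the data were seen. Alternatives for start sites, gene lists and the Kdm5a gene were not run, for lack of an mm9 annotation. Neither f/f sample could be left out by name, since the labels do not tie lanes to samples, so each lane alone was used. If each lane holds 1 sample, these settings leave out each sample in turn. No paired analysis was possible because the KO and input groups hold 1 sample each. Depth limits single peaks most: the median peak holds 3 KO reads and 1 input read.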

Other observations

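The KO ChIP lay above the input in every score class of the peaks, with pooled RPM ratios of 2.12, 2.03, 2.20 and 1.84 from the highest-scoring class to the lowest. The median peak held 3 KO reads and 1 input read, and what share of peaks would pass at that depth was not simulated. Measured against the input, 137 of the 3093 peaks (4.43%) were at least 2-fold higher in the KO ChIP with an interval above 1, and 1 was in the opposite direction. That peak, on chromosome 5 from 130363147 to 130363758, had 67 f/f reads, 0 KO reads and 6 input reads. Its f/f over KO fold was 15.3 by the floor of 3 reads, with a lower limit of 12.1 by the exact interval. Of the 137, 84 had an f/f over KO fold under 2, a count that chance gains of KO reads raise because both measures use them. Chromosomes 6 and 11 held 42 of the 137, or 10.05% of their peaks against 3.55% elsewhere, beside KO over f/f read ratios of 1.43 and 1.31 along these chromosomes. The peak on chromosome 6 from 29698243 to 29699149, named after its values were seen, had 28.7 f/f, 18.5 KO and 6.21 input RPM, so that its KO level was 2.98 times the input (2.20 to 4.08) and its f/f level 1.55 times the KO (1.30 to 1.86), with no correction for the higher KO read share of chromosome 6. The peak on chromosome 3 from 5860582 to 5860871, named in the same way, had 11.8, 6.37 and 1.85 RPM, with a KO level 3.44 times the input (1.98 to 6.27). Its f/f reads came mostly from lane 1, at 22.3 RPM, while lane 2, at 6.53 RPM, was close to the KO ChIP. This peak and the chromosome 6 peak had 17 and 57 input reads. Both lie far above the limit used above to leave out peaks, 3 times the genome mean of 3.47 input reads per kb. At the peak on chromosome 5 from 72925914 to 72926307, also named after its values were seen, the f/f ChIP had 17 reads and the KO ChIP 11, a ratio of 1.06 after scaling (0.468 to 2.502), with no input read. The lanes lay on either side of the KO level of 1.13 RPM, with 2 reads (0.425 RPM) in lane 1 and 15 reads (1.58 RPM) in lane 2.

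Of the 3093 peaks, 140 (4.53%) had another within 10 kb, where 1000 uniform random placements on the same chromosomes gave a median of 82 and at most 120. These placements took no account of mappable sequence or uneven read density, which would bring peaks closer together. They formed 70 pairs and no larger group. Both peaks passed over KO in 29 pairs, 1 peak in 20 pairs and neither in 21. One pair, named after its values were seen, on chromosome 2 from 168055584 to 168056674, had 9.64 f/f RPM in all against 0.924 in the KO ChIP and 0.545 in the input. A pair on chromosome 1 from 85231179 to 85240181, named in the same way, had 0.915, 1.23 and 0.218 RPM.

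A single 10 kb window on chromosome 2, from 98500001 to 98510000, took 1.33% of f/f reads, 1.00% of KO reads and 0.782% of input reads, and touched no peak. In the 20 peaks narrower than 140 bp, 221 f/f reads were counted without a shift and 57 with the shift of 100 bp. The 4 peaks left with no f/f read lay on chromosome 17 from 56145244 to 56145372, chromosome 4 from 96958740 to 96958876, chromosome 5 from 7194980 to 7195105 and chromosome 6 from 114443625 to 114443758, and held 54 f/f reads without a shift. The X chromosome had a read density of 0.323, 0.339 and 0.393 times that of the autosomes other than 6 and 11 in the f/f ChIP, KO ChIP and input.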
